A study of Mus musculus with 22 samples.

How the data were processed

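RNA from whole brains of mice labelled Agtr2 knockout and of control mice was compared on 22 dual-colour Agilent arrays, each carrying the RNA of 1 knockout and 1 control animal labelled with Cy3 and Cy5. Per the labels' protocols, total RNA came from frozen slices of whole brain, was treated with DNase, and was amplified and labelled with a linear amplification kit. The labels give 8 knockout replicates and 6 control animals at embryonic day 15 (E15), on 14 arrays, and 4 knockout and 4 control replicates at postnatal day 1 (P1), on 8 arrays. Every replicate had both dye orientations except 2 of the E15 replicates, numbers 3 and 4, which had 1 array each. The 6 E15 controls serve 8 knockout replicates, so replicates 1, 4 and 7 and replicates 2, 3 and 8 are linked through shared control animals. Replicates 5 and 6 each have a control of their own, and the arrays of E15 replicates 1 and 2 name different control animals in their 2 orientations.

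Per the file headers, the deposited scanner files hold the mean pixel intensity of each spot and the median intensity of its local background in both channels, with no normalization, together with processed intensities from which the scanner software subtracted a spatial detrend surface and which it dye-normalized by LOWESS on rank-consistent probes. Per the file headers, the deposited log10 ratios are the log10 of red (Cy5) over green (Cy3) processed signal. The deposited matrix held the same log10 ratios, within 0.005 of the scanner files and not turned in sign for dye orientation, as a comparison of the files showed. Steps between tissue and scan other than those above are not recorded in the labels or headers.

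The mean signals were corrected for the median local background by normexp with an offset of 50 and normalized within each array by loess, with control spots given no weight. Spots that the scanner software marked as outliers were set to missing, spots of 1 probe were averaged, and log2 ratios were turned to knockout over control. The arrays of a knockout replicate were averaged to 1 value. For the 2 replicates with 1 array, the mean dye effect of the other 6 replicates was subtracted for each probe. Of 41174 probes, 33514 had a gene symbol, giving 21107 symbols: 21445 probes were named through their accession, 5431 through the symbol and 4636 through a synonym in a table of mouse genes of assembly GRCm38.p6, and 2002 kept the name in the files. A gene was represented by the probe with the highest mean intensity over all 22 arrays, and probes with no symbol were tested as themselves. The lowest and highest value over all probes of a gene are given where probes disagreed. Features were kept where they were well above background, as the scanner software marks it, in at least 50% of the channels of the age.

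Signal over background sets the precision of an array. The share of spots well above background ran from 68.6% to 93.0% over the E15 arrays and from 62.3% to 95.1% over the P1 arrays, and the number of arrays limits what can be detected. Spots marked as outliers numbered 52 to 381 per E15 array and 287 to 3343 per P1 array.

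Each knockout comparison was tested against 0 on the replicate values with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with statmod 1.5.0 (data.table at version 1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The E15 fit took the control-sharing set as a random block (duplicateCorrelation, estimated on every 8th feature with complete values; consensus correlation 0.0589), and the P1 fit had no block. The difference between the ages was the contrast of the 2 means, with the control-sharing set as a block (consensus correlation 0.0814). The pairing of knockout and control comes from the array on which both were hybridized. For the comparison of the ages in control animals, channels were separated after Aquantile normalization over all 22 arrays and averaged per animal, and features passing the filter at either age were tested. P values were adjusted by Benjamini-Hochberg over all features of a comparison, with a threshold of 0.05.

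Lists of genes, 26 in number, were fixed from textbook knowledge before the data were examined, as were the designs, the alternatives named as planned and the rule for the genes named. They cover the angiotensin system, X-linked intellectual disability genes, neural progenitors, cell cycle, postmitotic neurons, synapse and glutamate signalling, GABA neurons, monoamine neurons and neuropeptides, the oligodendrocyte lineage, astrocytes, microglia and macrophages, endothelium and pericytes, meninges and fibroblasts, choroid plexus, erythroid cells, other tissues in the dissection, hypoxia, immediate early genes, heat shock, protein phosphatases and MAPK feedback, apoptosis, Wnt signalling, TGF-beta and BMP signalling, ribosomal proteins, oxidative phosphorylation and sex-linked genes. Lists were tested with limma's cameraPR at a preset correlation of 0.01, used because values are missing for some features, and with camera at an estimated correlation and fry on features measured in every sample. List p values were adjusted over the 26 lists of a comparison. A further 4 lists (skeletal muscle, bone and cartilage, forebrain, hindbrain and cord) were written after the data had been seen and were adjusted among themselves.

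The rule for named genes took, for each knockout comparison and for the difference, the 12 largest rises and 12 largest falls past the threshold among genes with a symbol and, for the knockout comparisons, with 1 sign in every replicate. Where fewer than 20 were found, the genes with the lowest unadjusted p and 1 sign in every replicate were added up to 20. The age comparison took the 12 largest rises and 12 largest falls. Up to 4 members per list with the lowest unadjusted p were available for naming, and the angiotensin system and the sex-linked genes always.

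The model was tested on simulated replicate values, drawn as independent normal noise with each gene's SD and missing values taken from the real arrays. The noise held no correlation between genes, no shared controls and no difference of tissue, so the rates need not hold for the real arrays. Among features with no missing value, 100 genes were changed by 0.5 and 100 by 1 on the log2 scale. At E15, 71% and 96% of them were recovered with 16 false calls over 24126 features. At P1, 45% and 83% were recovered with 6 false calls over 24916. For the difference between the ages, 47% and 76% were recovered with 8 false calls over 23547, and for the age comparison 49% and 88% with 10 false calls over 25474.

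Alternatives fixed before the data were examined changed the background correction, the normalization, the filter on dim probes, the outlier-marked spots, the prior of the variance, the source of the values (scanner processed signals or the deposited log10 ratios), the block for shared controls, the treatment of the single-orientation replicates, the pairing, the scan day and the replicates entered. Alternatives added after the data had been seen required both dye orientations and at least 3 replicate values, left out E15 replicates 4 and 8, took the scan days apart, took list medians as covariates, left out probes marked on any array, and required 3 animals per age. No array was left out of the comparisons. Permutation tests of correlations used all orders of the replicates or, with 10 or more values, 100000 permutations.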

Results

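The series measured RNA of whole mouse brain in animals labelled knockout for Agtr2, the X-linked gene of the type 2 receptor for the peptide hormone angiotensin II, against control animals. At E15 there were 8 animals labelled knockout and 6 controls on 14 arrays, and at P1 there were 4 and 4 on 8 arrays. The median signal of an array ran from 68.8 to 158.3 units at E15 and from 58.9 to 160.8 at P1, over a background of 34 to 49 and 33 to 43 units. Changes are log2 of knockout over control with their standard error (SE), and n counts knockout replicates unless control animals of the 2 ages are compared.

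Agtr2 RNA, the transcript of the targeted gene, did not differ detectably between the groups at either age. At E15 its change was -0.39 (SE 0.31, SD 0.93, n = 8, adjusted p = 0.806). Its values ran from -2.10 to 0.87, with 6 of 8 replicates below 0. At P1 its change was 0.11 (SE 0.08, SD 0.19, n = 4, adjusted p = 0.699), and 3 of 4 replicates lay above 0. Agtr2 was read by 1 probe, A_51_P437978, placed in the files at chromosome X from 19727379 to 19727438 on a build they do not state. Its signal was well above background on 13 of 14 E15 arrays in the knockout channel and on 13 in the control channel, and on 6 and 7 of the 8 P1 arrays. Whether the probe lies in the part of Agtr2 that was removed is unknown, so it does not check the labels of the animals. The Agtr2 signal of E15 controls ran from 61.9 to 1040 units and that of E15 animals labelled knockout from 58.4 to 157.9, while the P1 ranges were 53.8 to 94.3 and 48.5 to 126.5. In the 4 replicates scanned on E15 scan day 3 the Agtr2 change was -0.95, and in the 4 scanned on the other days 0.16. This division was made after the data had been seen. The lowest day 3 values came from arrays with control 1, at -2.52 (replicate 1) and -1.90 (replicate 4), with no dye effect subtracted. The other day 3 arrays gave 0.05 (replicate 1, control 6), -0.43 and 0.28 (replicate 2) and -0.20 (replicate 3). The division therefore cannot tell scan day from the use of control 1. Across the 6 E15 control animals the Agtr2 signal went with the level of genes of meninges and fibroblasts, the connective tissue around the brain. Pearson's r was 0.940 (exact permutation p = 0.00972, 0.0219 after adjustment) and Spearman's rho 0.943 (exact permutation p = 0.0167, adjusted 0.0300), in a family of 9 relations, and r was 0.927 without the 2 animals farthest from the median level. Across the 8 animals labelled knockout r was 0.580 (exact permutation p = 0.121, adjusted 0.121), rho 0.214 (exact permutation p = 0.619, adjusted 0.619) and r without the 2 farthest 0.138. No scan day held 6 animals of 1 group, so these relations have no value within a scan day.

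**Figure D1:**
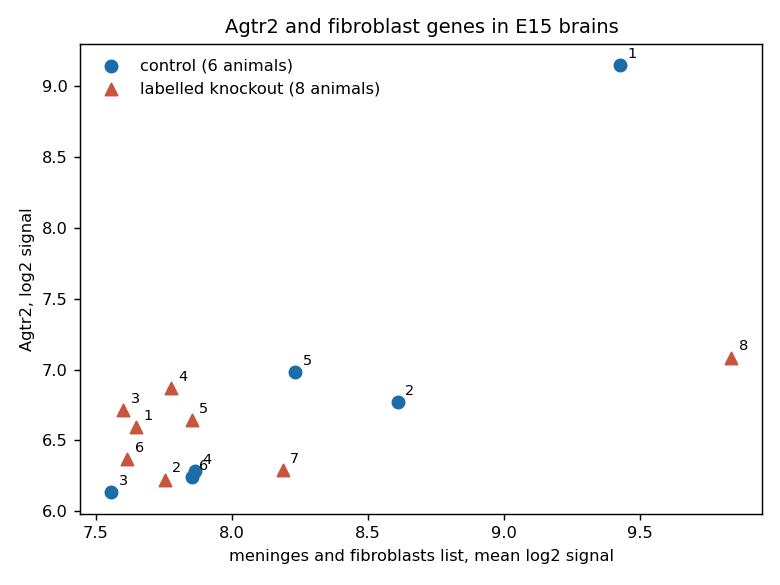
Log2 signal of Agtr2 (vertical) against the mean log2 signal of the meninges and fibroblasts list (horizontal), 1 point per E15 animal, numbered as in its group. Control 1 had an Agtr2 signal of 9.15 at a list level of 9.43, and knockout 8 a signal of 7.08 at a list level of 9.84.

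At E15, the middle of neuron production, 5 lists of genes passed the threshold with small shifts at a preset correlation and 0 with an estimated correlation. No single gene passed. Genes of ribosomal proteins, the parts of the machinery that makes proteins, were lower as a list, with 34 of 40 members below 0 and a median of -0.11. Their replicate medians ran from -0.54 in replicate 4 to 0.24 in replicate 8. The meninges and fibroblasts medians, given below, were lowest and highest in the same replicates. Both lists lay below 0 in replicates 1 to 4 and 6, and no correlation between them was computed. Genes of the cell cycle were lower as well, with 27 of 33 members below 0 and a median of -0.10. Genes of synapses and glutamate signalling were higher as a list (19 of 28 members above 0, median 0.08), as were genes of X-linked intellectual disability (27 of 38, median 0.07) and of GABA neurons, the inhibitory neurons of the brain (19 of 29, median 0.09). The adjusted p values were 0.00960 for the ribosomal list, 0.00960 for the synapse list, 0.0103 for the cell cycle list, 0.0121 for the X-linked list and 0.0339 for the GABA list. Each of the 5 lists had an adjusted p = 0.853 with an estimated correlation. Rps14 and Rps16, proteins of the small ribosomal subunit, had changes of -0.60 (SE 0.21, below 0 in 7 of 8) and -0.34 (SE 0.12, below 0 in 8 of 8), with adjusted p = 0.761 as for the other list members given here. Plk1, a kinase that drives mitosis, had a change of -0.42 (SE 0.09, below 0 in 7 of 8), and Aurkb and Cdc20, which act in chromosome separation, had -0.26 and -0.23 (Cdc20 -0.14 without replicate 4). Syt1, the calcium sensor of transmitter release, had 0.39 (SE 0.10, above 0 in 7 of 8). Phf8, a histone demethylase, had 0.27 (above 0 in 8 of 8), Gria3, a glutamate receptor subunit, 0.18, and Gabra2, a subunit of the GABA receptor, 0.33 (above 0 in 8 of 8). No list member passed the threshold over all genes, and Plk1 (cell cycle) and Bmpr2 (TGF-beta and BMP signalling) passed when adjusted over the list alone.

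The largest differences between the animals of an E15 pair lay in genes of tissue around the brain, and they went both ways. The meninges and fibroblasts list had a median of -0.14 with 19 of 20 members below 0 (adjusted p = 0.260), and its replicate medians ran from -1.69 in replicate 4 to 2.12 in replicate 8. Col1a2, a collagen of connective tissue, had a change of -0.85 with an SE of 0.90 and an SD of 2.67, and ran from -1.58 without replicate 8 to -0.43 without replicate 3. The skeletal muscle list, written after the data had been seen, had a median of -0.53 with 16 of 16 members below 0 (adjusted p = 0.117) and replicate medians from -3.76 to 3.26. Of the other E15 lists fixed before the data were examined, none passed the threshold, with adjusted p from 0.118 to 0.996. Medians below 0 were found for microglia and macrophages (-0.06), other tissues in the dissection (-0.07), immediate early genes (-0.05), hypoxia (-0.05), heat shock (-0.04), choroid plexus (-0.04), astrocytes (-0.03) and the oligodendrocyte lineage (-0.03). Postmitotic neurons had a median of 0.09, sex-linked genes 0.03, and the TGF-beta and BMP list 0.00082 against a mean of -0.0080. Smaller medians were found for Wnt signalling (-0.02), apoptosis (-0.02), protein phosphatases and MAPK feedback (-0.02), neural progenitors (-0.01), monoamine neurons and neuropeptides (-0.01), oxidative phosphorylation (-0.01), endothelium and pericytes (0.01), and erythroid cells (-0.01, with a mean of 0.00018). Of the lists written after the data had been seen, hindbrain and cord had a median of 0.07 (15 of 18 above 0, adjusted p = 0.257), bone and cartilage -0.04 (adjusted p = 0.645) and forebrain -0.03 (adjusted p = 0.856). The angiotensin system, the pathway of the targeted receptor, had a median of -0.01 over 22 members (adjusted p = 0.837), among them Ace, the enzyme that makes angiotensin II, at -0.14 (SE 0.09, below 0 in 7 of 8; -0.05 without replicate 3).

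Among single genes at E15, limma called 0 of 24126 features, with 1553 at an unadjusted p under 0.05 (948 higher and 605 lower), where 1206 would be expected by chance alone. Bmp2k, a kinase induced by bone morphogenetic protein, had the lowest adjusted p, 0.272, with a change of 0.55 (SE 0.06, above 0 in 8 of 8), while its 3 probes ran from -0.0033 to 0.56. With scanner processed signals its change was 1.48 and with deposited values 1.48, and it was called (adjusted p = 0.0337 and 0.0338, within 0.0337 to 1 over its alternatives). Pla2g4b, a phospholipase, followed with -0.50 (SE 0.07, below 0 in 8 of 8, adjusted p = 0.503). Ube3a, the ubiquitin ligase lost in Angelman syndrome, had 0.37 (SE 0.06, above 0 in 8 of 8, adjusted p = 0.761). Of the other genes taken by the rule, all with adjusted p = 0.761, Mrps12 and Gemin7 had -0.42 and -0.21, and Cul5, Fam133b, Zfp521, LOC434630, Cit, Nexmif, Bmpr2, L3mbtl3, Pcdha9, Map3k2, Ccar1, 5430405H02Rik, Fam160b1, Anks1b and Ddx5 had changes from 0.20 (Cit) to 0.78 (Fam160b1). For 99.0% of the features the 95% interval of the change lay within 2-fold. The list results rested on single replicates. No list passed without replicate 1 or without replicate 4, 3 passed without replicate 2, replicate 3 or replicate 6, and 10 passed without replicate 8. Pla2g4b was called (-0.55) without replicate 1. In replicates 5 to 8 alone, the scan days 1 and 2, the ribosomal, GABA and X-linked lists had the opposite direction, a division made after the data had been seen.

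**Figure D2:**
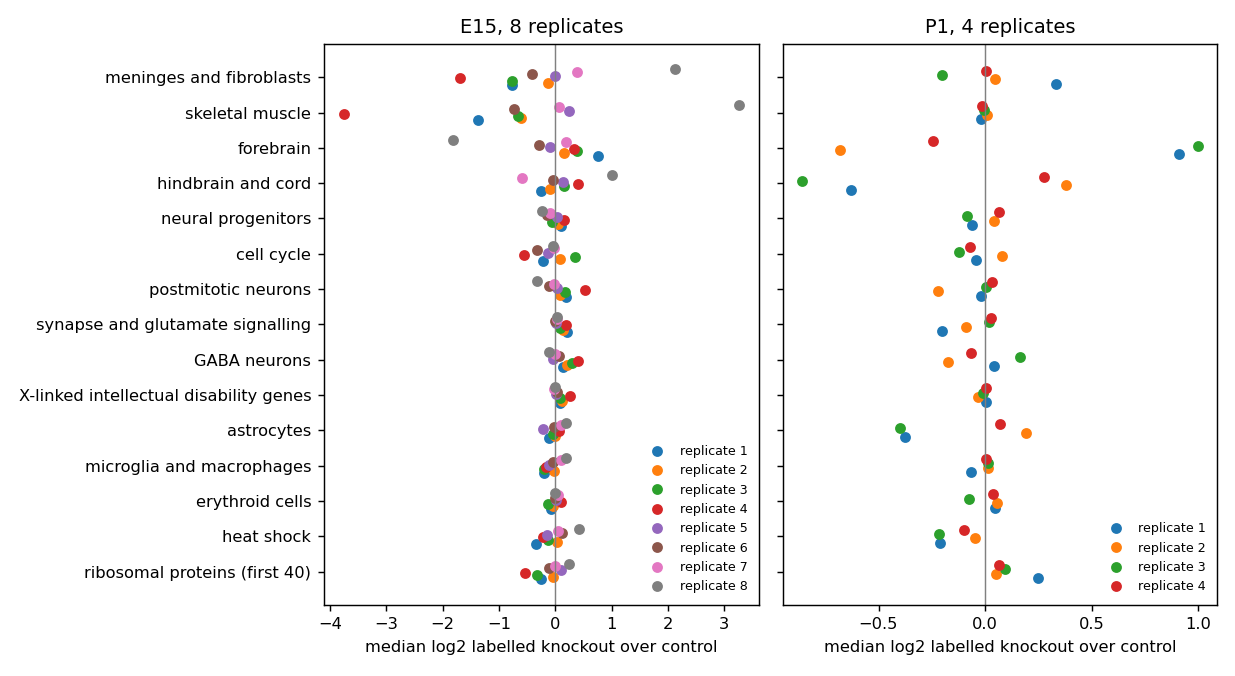
Median log2 ratio of knockout over control of 15 gene lists in each E15 and P1 replicate, 1 point per replicate. The skeletal muscle median runs from -3.76 to 3.26 between E15 replicates 4 and 8, and the forebrain median at P1 runs from -0.68 in replicate 2 to 1.00 in replicate 3.

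At P1, in the newborn brain, the heat shock list was lower and the ribosomal protein list higher in the brains labelled knockout at a preset correlation, 0 lists passed with an estimated correlation, and no single gene passed the threshold. Of 15 heat shock genes, which encode chaperones that fold proteins, 12 lay below 0 with a median of -0.20 (adjusted p = 0.0115; adjusted p = 0.747 with an estimated correlation). Of 40 ribosomal genes, 30 lay above 0 with a median of 0.14 (adjusted p = 0.0115; adjusted p = 0.747 with an estimated correlation). Hspa8, the chaperone made in unstressed cells, had a change of -0.47 (SE 0.07, below 0 in 3 of 3 values), Hsp90ab1, another abundant chaperone, -0.45 (SE 0.14, below 0 in 4 of 4; -0.28 without replicate 1), and Hspe1, a mitochondrial chaperonin, lay on the other side at 0.28 (SE 0.06, above 0 in 4 of 4). Rps13 of the small ribosomal subunit had 0.43 (SE 0.10, above 0 in 4 of 4), while Rpl4 of the large subunit had -0.71 (SE 0.17, below 0 in 4 of 4). These members had adjusted p from 0.460 to 0.473. The astrocyte list had a median of -0.12 with 15 of 18 members below 0 (adjusted p = 0.0759). It split by replicate, with medians of -0.38, 0.19, -0.40 and 0.07 in replicates 1 to 4. In each replicate the forebrain list, given below, lay on the opposite side of 0. Among the astrocyte members below 0 were Aqp4, the water channel of astrocytes, at -0.25, and Apoe, a lipid carrier, at -0.81 with an SE of 0.48. Without replicate 1 these were -0.11 and -0.25, and without replicate 2 they were -0.36 and -1.16. Adjusted over the list alone, Hspa8, Hspe1, Igf2 at 0.25, a growth factor of meninges and fibroblasts, and Cox6a1 at 0.31, a part of the respiratory chain, were among the members that passed. Over all genes, 0 of these members passed.

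The other P1 lists gave adjusted p from 0.150 to 0.978. Cell cycle genes had a median of -0.05, synapse genes -0.08, monoamine neurons and neuropeptides -0.05, and Wnt signalling -0.01. Endothelium and pericytes had 0.07, choroid plexus 0.06, TGF-beta and BMP signalling 0.06, protein phosphatases and MAPK feedback 0.05, erythroid cells 0.04 and the angiotensin system 0.03. Median and mean or test differed in sign for 6 P1 lists. These were GABA neurons (median 0.04, mean -0.03), postmitotic neurons (median 0.02, test downward), apoptosis (median 0.0020, test downward), oxidative phosphorylation (median 0.0066, mean -0.017), meninges and fibroblasts (median -0.0057, mean 0.0098) and microglia and macrophages (median -0.0048, mean 0.022). The forebrain list, written after the data had been seen, had a median of 0.28 with 15 of 18 members above 0 (adjusted p = 0.341) and split by replicate, above 0 in replicates 1 and 3 and below 0 in replicates 2 and 4.

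Among single genes at P1, limma called 0 of 24916 features, with 2471 at an unadjusted p under 0.05 (1375 higher and 1096 lower), where 1246 would be expected by chance alone. Zdhhc2, an enzyme that attaches palmitate to proteins, had the lowest adjusted p, 0.354, with a change of -0.56 (SE 0.04, below 0 in 4 of 4). Wif1, an inhibitor of Wnt proteins, had -0.61, Rhbg, an ammonium transporter, -0.57, and Nsun2, an RNA methyltransferase, -0.31. Stat6, a transcription factor of cytokine signalling, had 1.21 from 3 values. Each value of Stat6 and Rhbg came from 1 dye orientation, with no dye effect subtracted. Mirg, 4632427E13Rik, Afdn, Fam98b, Tctex1, Ubn2, 2410005O16Rik, MGC65558, Mras, Ccnt2, Sirt7, 6430500C12Rik, 9630010G10Rik, 2610042L04Rik and Gm10925 had changes from 0.36 (Sirt7) to 0.93 (2610042L04Rik). All of these had adjusted p from 0.354 to 0.460. For 97.6% of the features the 95% interval lay within 2-fold. As at E15, the offset draws the ratios of dim probes towards 0. With the spots that the scanner software marked as outliers kept, Stat6, Rhbg and Wif1 turned sign (-0.04, 0.03 and 0.09). A joint fit of both ages by limma called 113 genes (11 higher and 102 lower). Where a feature had 1 P1 value, its SE in that fit held no spread between P1 replicates. Stat6, with values of 1 dye orientation only, had the lowest adjusted p of the joint fit (0.000227). The number of lists past the threshold was 1 without replicate 1 (heat shock; the ribosomal list had adjusted p = 0.140, within 5.15e-06 to 0.747 over its alternatives), 5 without replicate 2 and 4 without replicate 4.

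The difference between the ages asked whether the effect at P1 departed from that at E15, as the P1 change minus the E15 change. Ribosomal protein genes turned upward from E15 to P1, with 33 of 40 members above 0 and a median difference of 0.24 (adjusted p = 0.000597; adjusted p = 0.673 with an estimated correlation). The E15 medians of this list were lowest and highest in the same replicates as those of meninges and fibroblasts, as given above. Genes of synapses and glutamate signalling turned downward, with 22 of 28 below 0 and a median of -0.15 (adjusted p = 0.000597; adjusted p = 0.228 with an estimated correlation). Genes of X-linked intellectual disability turned downward, with 29 of 38 below 0 and a median of -0.07 (adjusted p = 0.0357; adjusted p = 0.268 with an estimated correlation). Grm5, a glutamate receptor, had a difference of -0.65 (SE 0.17, adjusted p = 0.301), Syt1 -0.60 (SE 0.16, adjusted p = 0.309) and Syn2, a protein of synaptic vesicles, -0.50 (SE 0.14, adjusted p = 0.380). Rps14 had 0.77 (adjusted p = 0.826) and Rpl4 -0.75 (adjusted p = 0.833), on opposite sides within the ribosomal list. In the X-linked list, Gria3 had -0.26. The X-linked list was not past the threshold without E15 replicate 2 (adjusted p = 0.0731), E15 replicate 4 (0.126), P1 replicate 1 (0.107), P1 replicate 2 (0.0585) or P1 replicate 3 (0.0814), with 0.00279 to 0.896 over its alternatives, and 5 lists passed without E15 replicate 3, 5 or 8.

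Scn3b, a subunit of the sodium channel, fell between the ages in the knockout effect, with a difference of -0.62 (SE 0.11, adjusted p = 0.0339). That call did not hold under the stricter rule given below. Scn3b and the probe A_52_P474379 (-0.66) were among the few called features measured in both dye orientations in all 4 P1 replicates, and both were named after their values were seen. In all, limma called 73 of 23547 features, 7 higher and 66 lower, with 1375 at an unadjusted p under 0.05, where 1177 would be expected by chance alone. Of the 73, 70 had a P1 value from 1 dye orientation, and 69 had fewer than 3 complete P1 values, against 8.40% of all features tested. A P1 value from 1 orientation had no dye effect subtracted. Where a feature had 1 P1 value, its SE held no spread between P1 replicates. Fut7, Stat6 and Gip had 0 P1 values of both orientations. Among features with a symbol, the rises were led by Fut7, which makes a sugar ligand of selectins, at 1.41 (SE 0.11, adjusted p = 0.00386, 1 P1 value), Stat6 at 1.27 (SE 0.09, adjusted p = 0.000869, 3 P1 values), Adam28, a metalloprotease, at 1.18 (1 P1 value), Gip, a gut hormone, at 1.17 (3 P1 values), and Rnf170, a ubiquitin ligase, at 0.95 (1 P1 value). The falls with a symbol were led by Hc, complement component 5, at -0.98 (SE 0.13, adjusted p = 0.0241) and Myo1f, a myosin of white blood cells, at -0.98 (SE 0.10, adjusted p = 0.0136), followed by Dio3os, Slc5a2, Asb9, 9430002A10Rik, Pga5, Actrt3, Olfr654, Emilin3, Rgs14 and A530064D06Rik from -0.92 to -0.83, each from 1 P1 value. Of the list members called, Ren1, the enzyme renin, fell by 0.57 (adjusted p = 0.0246) and Wnt8b, a signalling protein of the forebrain margin, by 0.67 (adjusted p = 0.0186), both from 1 P1 value.

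When a P1 value had to come from both dye orientations and at least 3 replicates, a rule added after the data had been seen, limma called 0 features for the difference, with 929 at an unadjusted p under 0.05. Scn3b was then at -0.62 with an adjusted p of 0.692, within 0.00709 to 1 over its alternatives. Its SE stayed at 0.11 and its unadjusted p in limma was 7.32e-05. Its call in the main fit thus depended on the other features adjusted together with it. With the marked spots kept, 0 features were called by limma, 1041 had an unadjusted p under 0.05, and Rnf170 and 13 of the named falls, Wnt8b and Gh (0.17) among them, changed sign. The other named rises ran down to 0.115 (Fut7), 0.0179 (Stat6), 0.00844 (Adam28) and 0.00965 (Gip) over their alternatives. Leaving out 1 replicate gave 34 called features without E15 replicate 1, 36 without 2, 41 without 3, 48 without 4, 35 without 5, 43 without 6, 16 without 7 and 38 without 8, and 150 (129 higher and 21 lower) without P1 replicate 4. Adjusted over the list alone, Ren1, Wnt8b, Grm5, Syn2, Syt1, Gh and Lor were among those that passed, the last 2 in the list of other tissues with -0.36 and -0.40. Agtr2 had a difference of 0.50 (SE 0.45, adjusted p = 0.935), and 0.28 without E15 replicate 4. The other lists gave adjusted p from 0.0538 to 0.907, with GABA neurons and heat shock at 0.0538. The Wnt list had a median of 0.0047 against a mean of -0.035, and the sex-linked list a median of 0.014 with a downward test.

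The last comparison set 4 P1 against 6 E15 control animals, which were hybridized and scanned in separate series, so age and series cannot be told apart. Cell cycle genes were lower at P1, and genes of synapses, astrocytes, neurons and GABA neurons were higher, as lists at a preset correlation. Of 33 cell cycle genes 28 fell and 0 rose (29 and 1 when adjusted over the list alone), with a median of -0.90 (adjusted p = 2.94e-09; adjusted p = 0.253 with an estimated correlation). Mcm7 and Mcm2, parts of the helicase that opens DNA for replication, fell by 1.64 (SE 0.13) and 1.39 (SE 0.12), and Cdc20 fell by 1.40 (SE 0.14). Of 28 synapse genes 18 rose and 3 fell (19 and 4 when adjusted over the list alone), with a median of 0.51 (adjusted p = 1.29e-05; adjusted p = 0.101 with an estimated correlation). Syn2 rose by 1.72 (SE 0.17; the lowest of its 3 probes had 0.09), Gria2, a glutamate receptor subunit, by 1.61 (SE 0.15; its other probe had 0.17), and Grm5 by 2.34 (SE 0.18; its other probe had 0.02). Of 18 astrocyte genes 12 rose and 0 fell (12 and 1 when adjusted over the list alone), with a median of 0.83 (adjusted p = 4.56e-05; adjusted p = 0.101 with an estimated correlation). Apoe rose by 2.95 (SE 0.21), Fgfr3, a growth factor receptor of astrocyte precursors, by 2.34 (SE 0.13; another of its probes had 0.01), and Slc1a2, the astrocyte glutamate transporter, by 0.82, while its 5 probes ran from -0.82 to 0.82. The probes of Grm5, Fgfr3 and Apoe belonged to the 455 bright P1 probes given below, with outlier marks on 0, 1 and 2 of the 8 P1 arrays, and Apoe had no other probe.

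Postmitotic neuron genes rose as a list, 8 of 25 rising and 1 falling in both adjustments, over all genes and adjusted over the list alone (adjusted p = 0.00764; adjusted p = 0.393 with an estimated correlation), with Nefm, a neurofilament, at 1.41, Stmn2, a regulator of microtubules, at 1.14, and Ncam1, an adhesion molecule of axons, at 0.82. GABA neuron genes rose, 15 of 29 rising and 7 falling (16 and 9 when adjusted over the list alone; adjusted p = 0.00764; adjusted p = 0.393 with an estimated correlation). Sst, a peptide of interneurons, rose by 1.08, and Gabrb1, a subunit of the GABA receptor, by 0.82. Genes of meninges and fibroblasts fell, 10 of 20 falling and 1 rising (16 and 1 when adjusted over the list alone; adjusted p = 0.00820; adjusted p = 0.511 with an estimated correlation), with Foxc1 and Foxd1, transcription factors of the meninges, at -1.18 and -0.92, and Aldh1a2, which makes retinoic acid there, at -0.56. The E15 controls differed in this tissue, with Col1a1 signals of 14.32 and 13.38 in controls 1 and 2 against 9.07 to 11.04 in the other 4, and the skeletal muscle list had a median of -1.12 with 15 of 16 members below 0 (adjusted p = 0.433). Neural progenitor genes fell, 14 of 23 falling and 4 rising (15 and 4 when adjusted over the list alone; adjusted p = 0.0391; adjusted p = 0.381 with an estimated correlation). Tead2, a transcription factor of growing tissue, fell by 1.62, Vim and Nes, filament proteins of radial glia, by 1.69 and 1.31, and Fabp7, a fatty acid binder of radial glia and astrocytes, rose by 1.54. Ribosomal protein genes fell, 11 of 40 falling and 0 rising (10 and 0 when adjusted over the list alone; adjusted p = 0.0178; adjusted p = 0.511 with an estimated correlation), with Rps21 at -1.17, Rps14 at -1.06 and Rps6 at -0.67. Agt, the precursor of angiotensin, rose by 1.33 (SE 0.09, adjusted p = 1.81e-06). Mtus1, which encodes a protein that binds the type 2 receptor, fell by 0.99, and Agtr1a, the type 1 receptor, fell by 0.32. Agtr2 had -0.78 (SE 0.50, adjusted p = 0.245), and -0.34 without E15 control replicate 1.

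In all, limma called 9633 of 25474 features, 3810 higher and 5823 lower at P1, and 1100 and 536 of them changed at least 2-fold. The 12 largest falls ran from -2.74 to -2.03. Among them were Mest at -2.74 (SE 0.37, adjusted p = 0.000294), Dlk1 at -2.18 (SE 0.63, adjusted p = 0.0205) and Cdkn1c at -2.08, imprinted genes of growth for which no list was tested. Hba-a1 and Hbb-bt, the globins of red blood cells, had -2.15 and -2.14, and 2210408I21Rik, 1810046K07Rik, 1700086P04Rik, LOC435744, Rcn3, Tlm and Dcaf12l2 ran from -2.51 to -2.03. The 12 largest rises, 4930402D18Rik, D5Ertd615e, Zfp933, Olfr212, Tmem200a, 4930554P06Rik, Fam167a, Adora3, Rnf144b, Ccrl2, 5830432F11Rik and Slc35f2, had values from 5.00 to 5.81 and belonged to 455 probes with a change above 2 and every P1 control above every E15 control when marked spots were kept. Of the P1 spots of these probes 74.9% carried outlier marks. Quantile normalization of all channels gave 4420 higher and 4337 lower features. The neural progenitor list missed the threshold without E15 control replicate 3 (adjusted p = 0.0558) or P1 control replicate 2 (0.0512), within 3.9e-08 to 0.381 over its alternatives. The ribosomal list missed it without P1 control replicate 4 (0.0623), within 2.49e-06 to 0.769, and Dlk1 (-2.07 and -2.13) did without P1 control replicate 2 or 3.

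**Figure D3:**
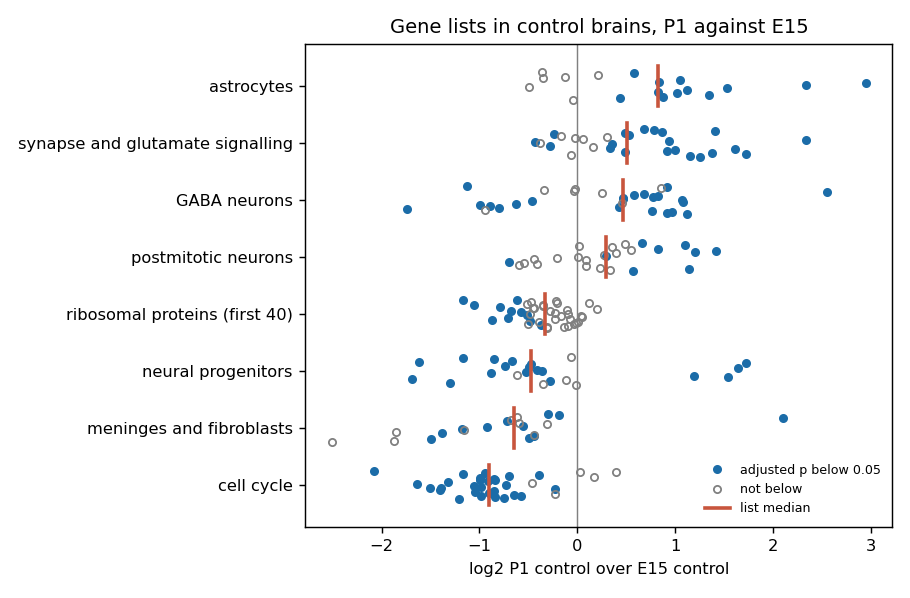
Log2 change of the members of 8 gene lists in control brains, P1 over E15, 1 point per gene, filled where the adjusted p is below 0.05, with the median of each list as a bar. The medians run from -0.90 for the cell cycle to 0.83 for astrocytes.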

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

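All tests of the patterns of surrounding tissue, brain region and bright probes were chosen after those patterns had been seen, and the counts over other splits of the samples were planned.

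In the E15 pairs, collagen and muscle genes differed strongly between the 2 brains, upward in knockout replicate 8 (meninges and fibroblasts 2.12, skeletal muscle 3.26) and downward in replicate 4 (-1.69 and -3.76). Knockout animal 8 had log2 signals of 14.12 for the collagen Col1a1 and 10.69 for the muscle actin Acta1, against 9.08 to 10.56 and 6.33 to 8.32 in the other 7 animals labelled knockout. High signals were also found in control 1 (14.32 and 11.37), which served replicates 1 and 4, and for Col1a1 in control 2 (13.38, Acta1 8.66). A candidate source is meninges or muscle left on some brains at dissection: the medians of the 2 lists, which share no gene, had a Spearman rho of 0.952 over the 8 replicates (exact permutation p = 0.00114, adjusted 0.00513), a Pearson r of 0.968 (exact permutation p = 0.000446, adjusted 0.00279), and r = 0.826 without the 2 farthest. An artefact of array or dye is argued against in replicate 8, whose 2 orientations gave 2.09 and 2.09 for meninges. For muscle they gave 3.24 and 3.07. Control 1 gave -1.34 and -1.53 for meninges on arrays of opposite orientation (replicates 1 and 4). Replicates 5 to 8 had 1 control animal in both orientations, which lay at most 0.381 apart for meninges and 0.614 for muscle. The ranges between these replicates were 2.55 and 3.86 and rested on replicate 8. Replicate 5 changed sign between its orientations (0.09 and -0.21 for meninges). An artefact stays open for replicates 2, 3 and 5 to 7. Over all 6 replicates with both orientations, of which 1 and 2 had another control animal in each, r between the orientations for meninges was 0.848 (exact permutation p = 0.0583, adjusted 0.0697), rho 0.543 (exact permutation p = 0.297, adjusted 0.382) and r without the 2 farthest 0.441. An effect of the knockout in 1 direction is argued against by 2 replicates with a median above 0.3 and 4 below -0.3. No scan day held 6 replicates, so none of the relations over replicates has a value within a scan day, and the permutations over E15 replicates take no account of the control animals that replicates share.

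Genes of forebrain and of hindbrain moved against each other within some pairs, as in E15 replicate 8 (-1.83 and 1.01), and at P1 the forebrain medians were 0.91, -0.68, 1.00 and -0.24 in replicates 1 to 4 and the hindbrain medians -0.63, 0.38, -0.86 and 0.27. Unequal shares of brain regions in the frozen slices may account for it: forebrain and hindbrain medians had rho = -0.706 over 12 replicates (permutation p = 0.0129, adjusted 0.0289), r = -0.831 (permutation p = 0.00062, adjusted 0.00279) and r = -0.658 without the 2 farthest, but at E15 alone r was -0.737 (exact permutation p = 0.0620, adjusted 0.0697), rho -0.333 (exact permutation p = 0.428, adjusted 0.481) and r 0.163 without the 2 farthest, so the relation is not established within E15, and P1 has too few replicates. A dye effect cancels in the mean of both orientations, and an artefact of single arrays as the whole cause is argued against by forebrain minus hindbrain in the 2 orientations of the 8 replicates with 1 control animal in both (r = 0.793, exact permutation p = 0.0223, adjusted 0.0339; rho = 0.857, exact permutation p = 0.0107, adjusted 0.0289; r = 0.869 without the 2 farthest), though sizes lay as far apart as 1.69 and 0.30 (forebrain, P1 replicate 1). An effect of the knockout in 1 direction at P1 is argued against by forebrain medians above 0.1 in 2 of the 4 P1 replicates and below -0.1 in 2. At E15 the forebrain and meninges medians had r = -0.851 (exact permutation p = 0.0226, adjusted 0.0339), rho = -0.714 (exact permutation p = 0.0576, adjusted 0.0864) and r = -0.477 without the 2 farthest.

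With marked spots kept, 455 probes had a change of more than 2 in the age comparison and every P1 control above every E15 control, with a median of 2.63. Those with a symbol covered 355 named genes. Defective spots in the lot of P1 arrays are a candidate source, since 74.9% of the P1 spots of the 455 probes carried outlier marks, against 3.84% for other probes at P1 and 0.272% for the same probes at E15. The 323 other probes of 196 of these genes had a median change of -0.0021. A probe that met the same rule was left out of these, so their median cannot decide whether some of the genes were higher at P1. In the age comparison 318 features represented by these probes were called higher.

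Of 94 groups of replicate values that were searched for a single value far from the rest, 9 held one, where chance gives about 1 in 20. At E15, replicate 3 had a median of -0.192 for the oligodendrocyte lineage (others -0.0543 to 0.0337), and replicate 8 had 0.244 for TGF-beta and BMP signalling (others -0.189 to 0.0148) and 1.80 for Fam160b1 (others 0.346 to 1.03). At P1, replicate 1 had 0.0741 for the angiotensin system (others 0.0243 to 0.0315), -0.0661 for microglia and macrophages (others 0.00482 to 0.0132) and -0.772 for Rhbg (others -0.528 to -0.489). Replicate 3 at P1 had -0.0742 for erythroid cells (others 0.0379 to 0.0542) and 0.919 for MGC65558 (others 0.566 to 0.624), and replicate 4 had 0.317 for 2410005O16Rik (others 0.458 to 0.485).

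The knockout effect differed between the ages by the test of the difference for 3 lists, with adjusted p of 0.000597 for ribosomal proteins, 0.000597 for synapse and glutamate signalling and 0.0357 for X-linked intellectual disability genes, and with 0.673, 0.228 and 0.268 as adjusted p with an estimated correlation.

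Other sign patterns or splits of the same replicates were fitted without the block for shared controls. At E15, 20 of 100 sign patterns of the 8 replicates gave as many features at an unadjusted p under 0.05 as the real one (1840, highest other 3044), so chance cannot be excluded. At P1 the 8 possible patterns are too few for a share under 0.05 (real 2471, highest other 2194, with 1 pattern as large, the real one). For the difference, 24 of 100 splits gave as many (1562, highest other 4838), so chance cannot be excluded, and a split with several times the real count points to a structure of the samples. For the age comparison 1 of 100 splits, the real one, gave as many called features (9633, highest other 1161), so a chance split of the controls can be excluded, while age and hybridization series remain confounded.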

How the results depend on the processing

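Alternatives that required both orientations, left out E15 replicates 4 and 8 or marked probes, took scan days apart or used covariates were chosen after the data had been seen, and the rest were planned. Unless a reason is given, the cause was not tested. The Agtr2 change at each age, its difference between the ages and its change in controls stayed on the same side of the threshold under the alternatives that gave a value, and the strictest filter on dim probes left Agtr2 out. Its change ran from -0.56 to -0.16 at E15 and from 0.05 to 0.19 at P1 when 1 replicate was left out, and with the mean of 0.16 on scan days 1 and 2 its sign at E15 turned. Over all its alternatives the Agtr2 change at P1 ran from 0.05 to 0.41.

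For single genes, E15 gave 0 to 1 calls when 1 replicate was left out and 1 call each with scanner processed signals, with the deposited values and with array values and a dye term. These were Pla2g4b (-0.55, without replicate 1, adjusted p 0.0301 in a range of 0.0301 to 1) and Bmp2k (1.48, 1.48 and 0.54, lowest adjusted p 0.0337 in a range of 0.0337 to 1). At P1, leaving out 1 replicate gave 0 calls by limma, and the joint fit of both ages gave 113, with 1874 at an unadjusted p under 0.05. The limit given above for features with 1 P1 value applies to the joint fit. For the difference, leaving out 1 replicate gave 16 to 150 calls. The count was 122 with scale normalization, 131 with no filter on dim probes, 2 with the strictest filter (Fut7 and Stat6), 14 with a trended robust prior, 113 with every probe, 6 unpaired with no replicate block (Fut7, Gip, Stat6, Myo1f, Slc5a2 and a probe without a name), 4 without E15 replicates 3 and 4 or without 4 and 8 (Fut7, Gip, Stat6 and Rhbg), 2 without 1 and 2 (Gip and Stat6) and 111 with array values and a dye term. By limma it was 0 with scanner processed signals (1253 at an unadjusted p under 0.05), deposited values (1256), marked spots kept (1041), means of control-sharing sets (1425), both orientations required (929) and marked probes left out (809). With marked spots kept, calls turned sign for Rnf170 (-0.0330), Hc (0.12), Myo1f (0.0371), Dio3os (0.0227), Asb9 (0.00455), 9430002A10Rik (0.0808), Pga5 (0.0523), Actrt3 (0.32), Olfr654 (0.15), Emilin3 (0.10), Rgs14 (0.0273), A530064D06Rik (0.0295) and Wnt8b (0.0114). Fut7, Stat6 and Gip kept their sign, but their differences ran down to 0.115, 0.0179 and 0.00965 over their alternatives. The age comparison gave 7430 to 10073 calls when 1 animal was left out and 1636 when a 2-fold change was also required.

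For the lists, E15 gave 0 to 10 past the threshold when 1 replicate was left out, 2 unpaired with no replicate block, 3 with the dye effect not subtracted, 1 without replicates 3 and 4, 0 without 1 and 2, 8 without 4 and 8, 9 on scan day 3 alone, 3 on scan days 1 and 2 alone, and 10 with forebrain minus hindbrain as a covariate. On scan days 1 and 2 alone the GABA, ribosomal and X-linked lists turned direction (adjusted p 0.537, 0.159 and 0.934, the ranges over alternatives being 5.97e-05 to 0.853, 1.46e-05 to 0.984 and 0.000554 to 0.934). P1 gave 1 to 5 when 1 replicate was left out, 1 with median centring, with deposited values or without marked probes, 4 with marked spots kept, 5 unpaired with no replicate block or with both orientations required, and 0 in the joint fit or with the covariate. The difference gave 2 to 5 when 1 replicate was left out, and 6 with means of control-sharing sets or with both orientations required. The age comparison gave 7 to 11 when 1 animal was left out. An estimated correlation left 0 lists in each comparison, fry's directional test 0 at E15, at P1 and for the difference and 17 for age, and its mixed test 0 at E15, 0 at P1, 1 for the difference and 26 for age. For the scan day, a term that set E15 replicates 1 to 4 (day 3) against 5 to 8 (days 1 and 2 together) was fitted, with 0 calls. That fit had no block for shared controls. No such term could be fitted at P1, where there was 1 scan day. Signal over background limits dim genes, Agtr2 among them.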

Other observations

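The test of Agtr2 against the level of surrounding tissue was chosen after its result was seen, and the test of the neighbours of Agtr2 was planned.

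In the comparison of P1 with E15 controls, where limma called 9633 of 25474 features, the lists below did not pass the threshold, and the counts are of single members. In the Wnt list 17 of 37 genes fell and 4 rose (19 and 6 when adjusted over the list alone; adjusted p = 0.135), with Fzd10, a receptor, at -1.40 and Lef1, a transcription factor of the pathway, at -1.38. In the erythroid list 6 of 14 fell and 1 rose (8 and 1 when adjusted over the list alone; adjusted p = 0.0606), with the embryonic globin Hbb-y at -2.01 and Alas2, which makes heme, at -1.16. In the hypoxia list 9 of 19 fell and 2 rose (adjusted p = 0.341; 9 and 2 when adjusted over the list alone), with the glucose transporter Slc2a1 at -1.35, and in the apoptosis list 10 of 24 fell and 1 rose (adjusted p = 0.0521; 10 and 1 when adjusted over the list alone), with Casp6, a protease of cell death, at -0.99. Olig1, a transcription factor of the oligodendrocyte lineage, rose by 1.25, while 2 of the 17 genes of that list rose and 2 fell (adjusted p = 0.580; 2 and 1 when adjusted over the list alone; median -0.04, mean 0.05).

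In oxidative phosphorylation 8 of 32 genes rose and 1 fell (adjusted p = 0.0583), in the immediate early genes 6 of 20 fell and 1 rose (0.0606), in protein phosphatases and MAPK feedback 11 of 22 fell and 3 rose (0.313), and in TGF-beta and BMP signalling 9 of 31 fell and 3 rose (0.304). In the angiotensin system 9 of 22 fell and 3 rose (0.544), in endothelium and pericytes 5 of 20 fell and 1 rose (0.252), in choroid plexus 6 of 18 fell and 2 rose (0.544), and in monoamine neurons and neuropeptides 4 of 23 rose and 3 fell (0.212). In the X-linked intellectual disability genes 9 of 39 rose and 6 fell (0.212), in microglia and macrophages 6 of 20 rose and 4 fell (0.544; median 0.0057, mean -0.042), in heat shock 5 of 15 rose and 4 fell (0.341), in other tissues in the dissection 6 of 29 rose and 5 fell (0.750), and in the sex-linked genes 1 of 5 rose and 1 fell (0.580). Adjusted over the list alone, the counts of rises and falls in these 13 lists were 7 and 1, 1 and 6, 3 and 11, 3 and 9, 3 and 9, 0 and 5, 2 and 6, 4 and 2, 9 and 6, 6 and 5, 5 and 4, 6 and 5, and 1 and 1, in the order given. Of the lists written later, skeletal muscle had a median of -1.12 with 0 of 16 genes called (adjusted p = 0.433), forebrain -0.57 (0.433), hindbrain and cord -0.23 with a mean of -0.0013 and an upward test (0.964) and bone and cartilage -0.10 (0.964).

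Over the 8 E15 replicates the Agtr2 ratio went with the meninges and fibroblasts median (r = 0.883, exact permutation p = 0.00474, adjusted 0.0142; rho = 0.952, exact permutation p = 0.00114, adjusted 0.00513; r = 0.761 without the 2 farthest). These permutations take no account of shared controls, and control 1 served both replicates 1 and 4. One hypothesis is that Agtr2 RNA in E15 control samples comes from tissue around the brain, which may carry the transcript in control animals and not in animals labelled knockout. The slope of Agtr2 on the list level was 1.58 over 6 controls and 0.23 over 8 animals labelled knockout, and the difference had a 2-sided exact permutation p of 0.0496 over all 3003 splits of the animals. With the skeletal muscle list as the level the slopes were 0.63 and 0.23 (exact permutation p = 0.145). Control 1 had both the highest Agtr2 signal and the highest list level of the 6 controls (9.15 and 9.43), and with 14 animals and 1 probe the question stays open.

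A second hypothesis was that DNA of the stem cell strain around the targeted gene changes the level of its neighbours on the X chromosome. Of the 20 measured genes nearest to Agtr2, 0 had an unadjusted p under 0.05 and 1 sign at both ages in limma, 1 (Rp2) had such a p at E15 and 0 at P1, and 0 were called at either age. A change of the neighbours that is common to both ages was not seen among these 20.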
